A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

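RNA of 6 plant samples was measured on Affymetrix rice arrays, 2 arrays for each of 3 groups: overexpression of OsSKIPa, suppression of OsSKIPa, and the wild type. Per the labels' protocols, seeds were germinated on selective medium for the transgenic lines, seedlings 10 days old were moved to hydroponics and plants were collected at 1 month. Total RNA was extracted with TRIzol and 6 µg of it was used to make biotinylated cRNA. The labels also state that OsSKIPa was checked by real-time RT-PCR in the transgenic plants before the arrays. Groups were taken from the source names in the labels, which call the transgenic samples biological repeats.

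The deposited values are signal intensity on a linear scale, 1 value for each of 57381 probe sets in each array. The software that summarised probes into probe sets is not given in the sources used here. Each array's mean after trimming 2% at either end was 500.06, as read from the values, so that the arrays had been brought to one scale before they were deposited. The largest ratio of array medians was 1.13, below the limit of 1.5 set beforehand, so the deposited scale was kept. A global scale makes each value relative to the rest of its array. A change in total RNA per cell cannot be seen.

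Values were tested as log2(value + 3.3), where 3.3 is the 10th percentile of all values, so fold changes are on that scale and understate the change of dim probe sets. The 123 control probe sets of the manufacturer were left out of the fit. Reporter probe sets stayed in. A probe set was tested if at least 2 of the 6 arrays lay above their own median, without regard to group. That left 30366 tested and 26892 out. A linear model over the 3 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), with 3 residual and 5.21 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. A fold is given as "at least" where both arrays of the dimmer group lie below the array median. The dim group was then raised to that median. The median is a bound chosen for this purpose, not a detection call.

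Probe sets were named through the platform's probe table and a gene table of assembly ASM3414082v1, used for names only. Of 57258 probe sets other than controls, 22436 had exactly 1 gene, 95 had several and 34727 were not in the probe table. All 17905 genes were found in the gene table. It gives no descriptions, and 2391 genes had a symbol or synonym other than a locus number or clone name. SNAC1, RAB16A, ADH1, NRT2.1, WRKY45 and PR1b, which were fixed for naming, had no probe set under those names and were not analysed here under them. A probe set that carries another name of one of these genes would not have been recognised. The gene fixed as LEA3 is given as LEA19.

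The groups, tests, alternatives, rule for named genes and themes of the gene lists were fixed before the data were examined. For each comparison, the rule names the 10 largest rises and 10 largest falls among called probe sets with 1 named gene whose groups do not overlap. Where fewer passed, places were filled by the smallest unadjusted p. It also names up to 4 members of each list past its threshold and a set of individually fixed genes. The themes of 38 lists were fixed, but the symbols that make up each list were matched once the symbol table had been seen, before any groups were compared. A further 19 gene families were taken from the symbol table, and none passed in any comparison. Lists used 1 probe set per gene, the brightest over all arrays, and were tested when they had at least 5 members, which left 36 of the fixed ones. The list test was limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. None of the camera calls held with an estimated correlation. That setting rests on the 3 residual degrees of freedom and has little power here, so its failures decide nothing about a shift. fry asks whether a list's genes move one way on balance and does not compare them with other genes.

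The overlap of the lines was set against 100 simulations of unchanged groups sharing the wild-type arrays, 50 for each of 2 ways of drawing the spread. The test was also run on simulated data with 200 changed probe sets in 20 simulations for each of the 2 comparisons with the wild type, among 30366 probe sets. With the spread drawn from the fitted prior, for overexpression against wild type 7.1% of 1.5-fold, 37.2% of 2-fold and 73.4% of 4-fold changes were recovered, with 5.1% of calls false. For suppression against wild type it was 6%, 37% and 73.2%, with 5.6% false. With the moderated spread, 20.3%, 55.1% and 82.5% were recovered for overexpression and 19.5%, 55% and 83% for suppression, and the shares of false calls were 11% and 10.5%. Under either spread, most 1.5-fold changes were missed.

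The alternatives tried were quantile normalization, scaling on the 75th percentile, pseudocounts of 1 and of the 25th percentile (12.3), no filter and a filter at the 75th percentile, eBayes without the trend and with robust priors, fits of only the 2 groups compared, the replicate number as a block, each array left out in turn, added 2-fold thresholds, and counts of genes. Counts without the reporter probe sets were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.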

Results

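Transcript levels were measured on Affymetrix rice arrays in 1-month-old rice plants (Oryza sativa, Japonica Group) of 3 groups. These were a transgenic line overexpressing OsSKIPa, which the series title calls a splicing factor, a line with suppressed OsSKIPa, and the wild-type cultivar Zhonghua11. Each group is represented by 2 arrays, 6 arrays in all, and this number limits the precision of every value. The labels call the transgenic samples biological repeats and the wild-type samples only controls. The suppression arrays carry the repeat numbers 1 and 3, and further repeats mentioned in the design text are not analysed here. The labels call the samples both shoots and whole plants, so the organs included are not settled. The overexpression plants were selected on hygromycin and the suppression plants on G418, so line and selection drug cannot be told apart. Each array was on the same scale, with a trimmed mean signal of 500.06, and array medians between 58.6 and 66.2. Between arrays of the same group, Pearson's r across probe sets was 0.972 (overexpression), 0.9706 (suppression) and 0.9725 (wild type), and between groups it ranged from 0.9515 to 0.9707 (probe sets are not independent replicates).

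OsSKIPa and OsSKIPb were not analysed here, because no probe set carried their names in the tables used, so the labels of the lines were not checked against the level of the targeted gene. Of the probe sets for inserted reporter sequences, 64 were on the array, 7 were bright enough to test and 4 passed the threshold in at least 1 comparison. The clearest reporter probe set of the overexpression line read 12415 and 14859.8 in that line and at most 12.7 in the other 4 arrays. The clearest one of the suppression line read 1670.6 and 1729.1 there and at most 23.6 elsewhere. The ratio of 3' to 5' signal of the actin control probe sets, a sign of RNA integrity, was 3.43 and 3.73 in the overexpression arrays, 2.82 and 2.89 in the suppression arrays and 2.86 and 2.75 in the wild type. The same ratio for GAPDH was 2.19 and 1.89, 1.66 and 1.9, and 1.87 and 1.81. The 18S rRNA control signal was 3673.9 and 3885.3 in the suppression arrays and between 4949.6 and 5450.5 in the other 4.

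The comparison of the overexpression line with the wild type asks which transcripts differ when OsSKIPa is raised. TIFY5, a member of the TIFY family that includes the JAZ repressors of jasmonate signalling, was the named gene with the largest rise. Its mean signal was 1213 ± 595 in the overexpression line and 1.9 ± 0.141 in the wild type (SD, n = 2 each), a log2 fold change of 7.78 ± 0.32 (SE; limma adjusted p = 0.000204). With the wild type raised to the array median, this is at least 18.2-fold. MT4C, a metallothionein-family gene, fell from 10660 ± 949 to 4337 ± 338 (SD), by 1.30 ± 0.11 on the log2 scale (adjusted p = 0.00797). Its call was lost without overexpression replicate 1 or wild-type replicate 1, with estimates between -1.39 and -1.2 over all fits that left out 1 array. TIFY5 kept its call in each of those fits (7.26 to 8.30).

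In all, 15 of 30366 tested probe sets passed in the overexpression line, 12 higher and 3 lower. Besides TIFY5 and MT4C, these were the reporter probe set (log2 fold change 11.14 ± 0.56, adjusted p = 0.000463, at least 218-fold), LOC4340325 (6.86 ± 0.44, adjusted p = 0.00168, at least 34.6-fold), LOC4331576 (4.29 ± 0.37, adjusted p = 0.00812, at least 2.21-fold), LOC4332910 (-1.59 ± 0.14, adjusted p = 0.00985), LOC4343074 (-1.92 ± 0.18, adjusted p = 0.0126) and 8 probe sets without a gene name that rose by 2.40 to 6.66, 7 of them by at least 2.23-fold to at least 12.1-fold where the wild type lay below the array median. These loci were added after their values were seen, because so few probe sets passed. With 1 array left out, LOC4340325 (6.02 to 7.70) and 1 of the 8 unnamed probe sets (5.99 to 7.32) kept their calls in each fit. The reporter (10.78 to 11.5) and 3 unnamed probe sets lost theirs without overexpression replicate 1, 2 unnamed ones without any 1 transgenic array, and 2 without any 1 array, with no change of sign. LOC4331576 (4.12 to 4.46) lost it without any 1 transgenic array, LOC4343074 (-2.02 to -1.82) without any 1 overexpression or wild-type array, and LOC4332910 (-1.68 to -1.49) without either overexpression array or wild-type replicate 1. The count was 5 without overexpression replicate 1 and 36 without wild-type replicate 2, of which 12 were higher and 24 lower. In all, 2159 probe sets had an unadjusted p under 0.05 where chance gives 1518. With eBayes without the variance trend, none passed the adjusted threshold in this line.

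Among the other named genes chosen by rank, none passed in the overexpression line. The ferric reductase gene 0sFRO1 read 1.04 ± 0.18 (adjusted p = 0.257), BGLU22 0.64 (0.429), and OsPP2C47 0.49 (0.477). AP2-1, AtNLP3, OsC3H37 and EXLA2 read 0.38, 0.48, 0.50 and 0.60, each with an adjusted p of 0.523, and OsPP2C71 and the blue-light receptor gene PHOT1A read 0.43 and 0.36, each with 0.552. On the lower side were OPR-1 at -1.57 (adjusted p = 0.13), MT1B at -0.73 (0.17), GPI-A at -0.87 (0.193), the ammonium transporter gene AMT1-2 at -1.63 (0.196) and the actin gene ACT2 at -0.44 (0.291). The remaining ones were atpB at -0.40 (0.392), HSFB2C at -0.85 (0.448), EXPB6 at -0.50 (0.45) and PCL1 at -0.62 (0.478).

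None of the 36 fixed gene lists shifted in the overexpression line by camera, with 0 past the threshold with an estimated correlation (lowest adjusted p = 0.752) and 0 by fry (lowest adjusted p = 0.616). A few lists did pass under other settings, which are given with the processing below. The jasmonate pathway list had 1 member higher (TIFY5) and 31 of 32 not past; adjusted over the list alone the counts were 1 higher and 1 lower, the median was -0.24 and the camera adjusted p was 0.0595. Of 48 iron and metal homeostasis genes, 1 fell (MT4C), 2 adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0647). In this line, the 6 root-preferred marker genes had a median of -0.39 (camera adjusted p = 0.127), with 0 called by limma, 3 with an unadjusted p under 0.05 and 1 lower adjusted over the list alone. AMT1-2 belongs to that list, and the silicon transporter gene Lsi1 read -0.52 (adjusted p = 0.696).

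**Figure D1:**
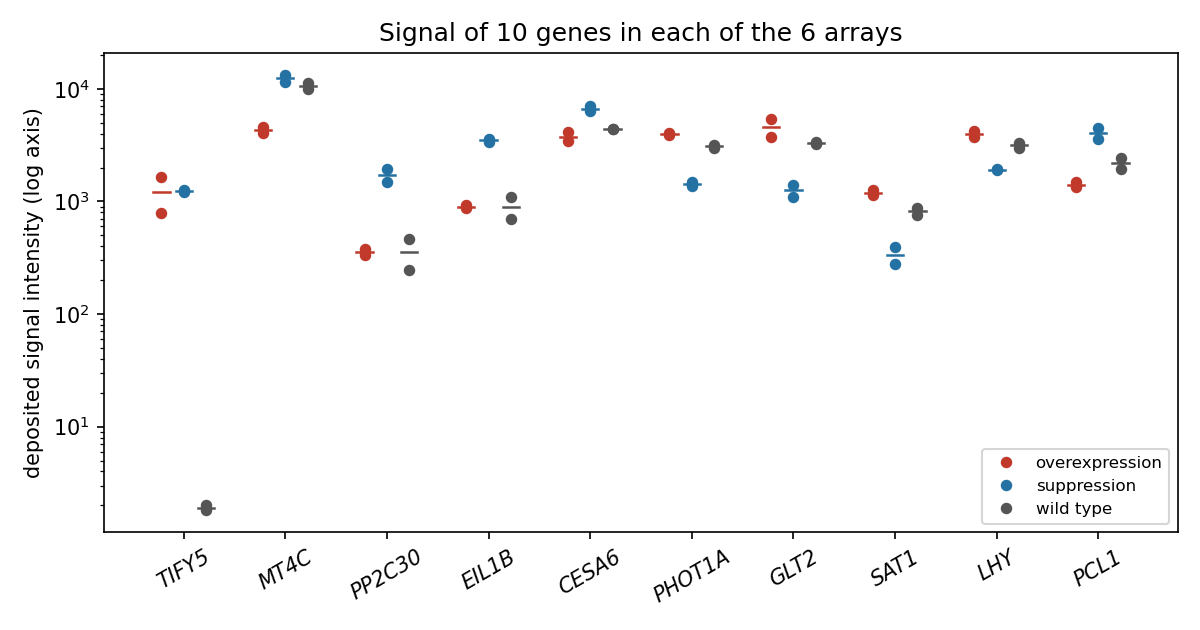
Deposited signal intensity (log axis) of 10 genes in each of the 6 arrays; points are arrays, dashes are group means and colours are groups. TIFY5 lies at 1.8 and 2 in the wild type and between 792.5 and 1634.3 in the transgenic lines, while PP2C30 and EIL1B are high in the suppression line and PHOT1A, GLT2 and SAT1 are low there.

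In the suppression line, compared with the wild type to ask what changes when OsSKIPa is lowered, TIFY5 was again raised, with a log2 fold change of 7.90 ± 0.32 (adjusted p = 0.00018, at least 19.9-fold). PP2C30, a type 2C protein phosphatase gene, rose 4.96-fold, from 354.9 ± 151 to 1706 ± 320 (SD, n = 2 each; log2 fold change 2.31 ± 0.27, adjusted p = 0.0064). EIL1B, of the EIN3-like family of ethylene-response transcription factors, rose 3.97-fold, from 897.3 ± 284 to 3487 ± 161 (adjusted p = 0.00335). PHOT1A, which encodes a phototropin blue-light receptor, fell from 3092 ± 118 to 1431 ± 89.8, by 1.11 ± 0.10 on the log2 scale (adjusted p = 0.00215). GLT2 fell from 3307 ± 102 to 1252 ± 207 (-1.41 ± 0.18, adjusted p = 0.00825).

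The other genes with the largest rises were the ammonium transporter gene AMT3-3 (1.81 ± 0.26), the potassium transporter gene HAK27 (1.76 ± 0.25), PP2C68 (1.37 ± 0.22), OsPP2C08 (1.36 ± 0.18), PXG (1.25 ± 0.25), OsABIL1 (1.16 ± 0.17) and mfs1 (1.15 ± 0.22), with adjusted p between 0.00878 and 0.0475. The other large falls were those of TGAL11 (-1.44), GLK2 (-1.42, at least 2.65-fold), the heat stress factor genes HSFB2C (-1.35) and HSFA2D (-1.01), SAT1 (-1.29), BZIP52 (-1.18), the germin-like gene GER3 (-1.09) and the laccase gene LAC7 (-0.99), with adjusted p between 0.0129 and 0.0409. Further probe sets of GLK2, a regulator of chloroplast development, read 0.24, -0.36 and -0.61, and a second one of HSFA2D read 0.11. In total 698 probe sets passed, 290 higher and 408 lower, and 5403 had an unadjusted p under 0.05 where chance gives 1518. At least 2-fold changes made up 131 of the rises and 191 of the falls. The groups did not overlap for 48.7% of probe sets, where chance gives 33.3%.

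TIFY5, PP2C30, EIL1B and PHOT1A kept their calls in the suppression line whichever array was left out. GLT2 (-1.58 to -1.24) and SAT1 (-1.54 to -1.05) lost theirs without either wild-type array, AMT3-3 (1.58 to 2.04) without those or suppression replicate 3, and GLK2 (-1.46 to -1.37), PXG (1.09 to 1.41) and TGAL11 (-1.67 to -1.21) without any 1 array. Each of the other genes named above for this line lost its call without wild-type replicate 2 and without at least 1 further array, with no change of sign. The count of 698 became 197 without wild-type replicate 1, 171 without wild-type replicate 2, 325 without suppression replicate 1 and 366 without suppression replicate 3, the remaining array of a group being assumed to vary like the other groups.

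The list of cellulose and hemicellulose synthesis genes had a median of 0.22 in the suppression line, with an upward shift by camera with the preset correlation (adjusted p = 0.0392) that did not pass with an estimated correlation (adjusted p = 0.785) or by fry (adjusted p = 0.0666). Of 26 measured, 2 rose, the cellulose synthase genes CESA1 (0.50 ± 0.08, adjusted p = 0.023) and CESA6 (0.59 ± 0.11, adjusted p = 0.0339), and 24 did not pass; 9 rose and 0 fell adjusted over the list alone. CSLC7 read 0.62 (adjusted p = 0.0508) and CESA8 0.35 (adjusted p = 0.11), and a second probe set of CESA1 read -0.15. CESA1 (0.43 to 0.58) lost its call without suppression replicate 3 or either wild-type array, and CESA6 (0.52 to 0.66) without any 1 suppression or wild-type array. The lower 18S control signal of the suppression arrays moved beside this list. The camera adjusted p of the list was 0.0608 without suppression replicate 1, 0.0619 without suppression replicate 3, 0.0688 without wild-type replicate 1, 0.056 after quantile normalization and 0.0754 with the mean of all probe sets of a gene.

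Common reference genes, a list of actin, tubulin, ubiquitin and similar genes, were shifted upward in the suppression line as well, with a median of 0.15 over 23 members (camera adjusted p = 0.016; adjusted p = 0.948 with an estimated correlation and 0.142 by fry). None passed singly by limma over all probe sets, 8 had an unadjusted p under 0.05, and 2 rose adjusted over the list alone. ACT2 read 0.34 (adjusted p = 0.071), TUBB3 0.30 (0.0794; other probe sets 0.60 and -0.34), TUBB2 0.26 (0.131) and UBQ2 0.24 (0.147). The list's adjusted p was 0.0657 without suppression replicate 1, 0.056 without wild-type replicate 1 and 0.0754 with the mean of all probe sets of a gene. The lower 18S control signal of the suppression arrays moved beside this group.

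Of 64 genes in the abscisic acid signalling list, 5 rose in the suppression line. They were PP2C30, PP2C68, OsPP2C08, OsABIL1 and OsPP2C09 (0.86 ± 0.17, adjusted p = 0.0472); 59 did not pass, and 8 rose and 1 fell adjusted over the list alone. The list as a whole did not pass (median 0.08, camera adjusted p = 0.0754; adjusted p = 0.785 with an estimated correlation). OsPP2C09 lost its call without any 1 array (0.64 to 1.08). In the list of circadian clock and flowering genes, with 14 members, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.588). The morning clock gene LHY fell by 0.71 ± 0.11 (adjusted p = 0.0158) and the evening gene PCL1 rose by 0.89 ± 0.15 (adjusted p = 0.026). LHY lost its call without any 1 suppression or wild-type array (-0.80 to -0.63), and PCL1 without suppression replicate 3 or either wild-type array (0.72 to 1.05).

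The light harvesting and photosystem genes with a matching symbol gave no calls in the suppression line. Of the 10 light harvesting and photosystem genes 0 passed by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05 (median -0.07, camera adjusted p = 0.5, fry adjusted p = 0.798). In chlorophyll synthesis, 1 of 16 fell, CAO (-0.77 ± 0.15, adjusted p = 0.044), and 1 rose and 2 fell adjusted over the list alone; the median was 0.01 and the mean -0.10 (camera adjusted p = 0.5). Among 28 phenylpropanoid and lignin synthesis genes, CAD3 rose (0.89 ± 0.10, adjusted p = 0.00552), LAC7 and CAD8C fell (-0.49 for CAD8C), and 25 did not pass; 3 rose and 5 fell adjusted over the list alone (median -0.07, camera adjusted p = 0.649). The 15 genes of the splicing machinery list had 0 limma calls against the wild type in either line. In the overexpression line 0 had an unadjusted p under 0.05. In the suppression line 3 had one, and 1 rose adjusted over the list alone (median -0.02, camera adjusted p = 0.967). The lists hold only genes with a matching symbol and may leave out other genes of the same process. Splicing itself was not measured. The 24 cell wall loosening genes had a median of -0.21, 0 limma calls, also adjusted over the list alone, and 5 with an unadjusted p under 0.05 (camera adjusted p = 0.0754). The root-preferred markers had a median of 0.13, 0 limma calls over all probe sets and 2 with an unadjusted p under 0.05 (camera adjusted p = 0.851), with 1 higher and 1 lower adjusted over the list alone. CAO (-0.95 to -0.59) kept its call only without suppression replicate 1 among the fits that left out 1 array, and CAD3 (0.84 to 0.93) lost its call without wild-type replicate 2 and CAD8C (-0.54 to -0.45) without any 1 array.

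The transgenic lines shared 13 called probe sets against the wild type, 11 higher and 2 lower in both, and 0 in opposite directions. With probe sets of the same target counted once, the rises numbered 8. The numbers given next count each probe set separately. Independent lists of these lengths would share 0.11 higher and 0.04 lower probe sets, and simulated unchanged groups measured against the same wild-type arrays gave a mean of 0.16 and at most 1. The shared rises included TIFY5, LOC4340325 (6.68 in the suppression line, at least 30.4-fold) and LOC4331576 (6.02, at least 7.45-fold), and the shared falls were LOC4332910 (-1.31) and LOC4343074 (-2.18). Because both comparisons use the same 2 wild-type arrays, which are too few to split, part of this excess may come from those arrays. Without overexpression replicate 1, 3 probe sets were called in both lines in the same direction and 2 in opposite directions. Without wild-type replicate 2, the 23 in the same direction were 11 higher and 12 lower. Across all tested probe sets the fold changes of the lines had a correlation of 0.3217, against 0.5022 in simulated unchanged groups, and a covariance of 0.0649, against 0.049 or 0.0642 depending on the spread simulated. Without wild-type replicate 1 the correlation was 0.473 and the covariance 0.1223, and without wild-type replicate 2 they were 0.482 and 0.1305. With 1 wild-type array left, its error enters both comparisons in full, which by itself raises the covariance. These values therefore cannot be set against the simulated ones. The covariance was 0.2057 with no filter and 0.0192 with the filter at the 75th percentile. No unchanged groups were simulated under these settings or with a wild-type array left out.

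**Figure D2:**
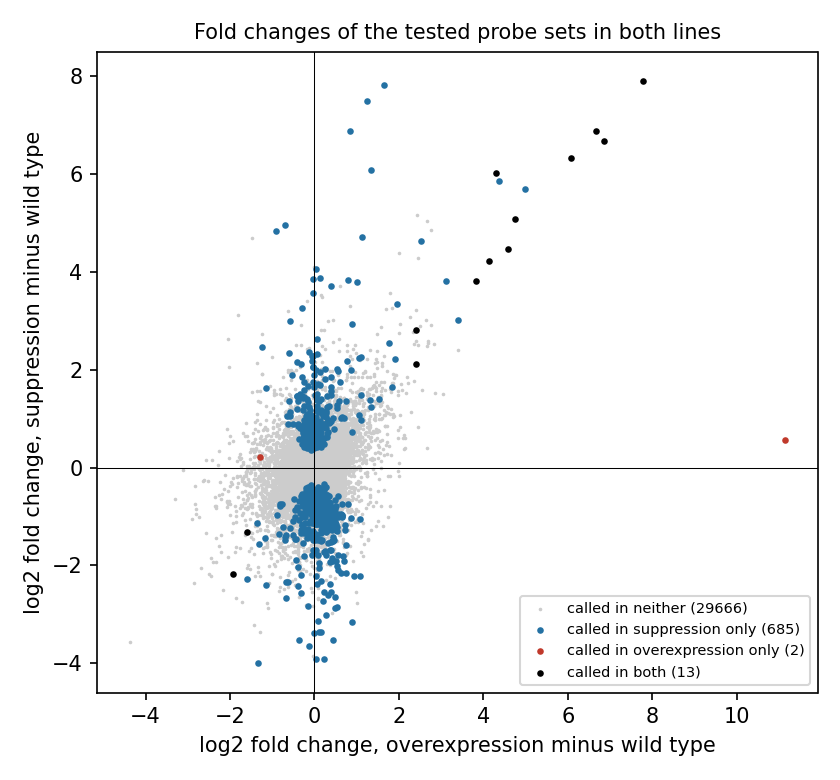
Log2 fold change against the wild type of each tested probe set, overexpression line on the horizontal axis and suppression line on the vertical axis; colour shows in which line a probe set was called. The 13 called in both lines lie in the upper right and lower left, and the reporter at 11.14 is called in the overexpression line.

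The 290 probe sets that rose with suppression had a median of 0.03 in the overexpression line and the 408 that fell had 0.11, both measured against the wild-type arrays by which these probe sets were chosen. The direct test between the lines passed for 231 of the former and 366 of the latter. It uses the suppression arrays by which they were chosen, and the number that an unchanged overexpression line would give was not computed.

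The lines were also set directly against each other, which leaves the wild-type arrays out of the difference. The ammonium transporter gene AMT1-2 was lower in the overexpression line, at 178.3 ± 75.9 against 1014 ± 153 in the suppression line (SD, n = 2 each; log2 fold change -2.54 ± 0.27, adjusted p = 0.00241), with 534.3 ± 23.3 in the wild type. PP2C30 (-2.25 ± 0.27, adjusted p = 0.00431) and EIL1B (-1.95 ± 0.19, adjusted p = 0.00187) were lower too. GLT2 (1.85 ± 0.18) and SAT1 (1.84 ± 0.18) were higher, each with an adjusted p of 0.00187, as was PHOT1A (1.47 ± 0.10, adjusted p = 0.000539). BURP16 differed by 3.77 ± 0.58 (adjusted p = 0.0107), with 525 ± 167 in the overexpression and 43.9 ± 39.9 in the suppression line.

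Further genes higher in the overexpression than in the suppression line were the dehydrin gene RAB21 (1.89; 1.05 without suppression replicate 3), HOX12 (1.53), the sugar transporter gene SWEET14 (1.52), KAO of gibberellin synthesis (1.5), MSRB1 (1.49, with -0.33 at its other probe set) and the lipoxygenase gene LOX2.1 (1.48; 0.95 without suppression replicate 1), with adjusted p between 0.00428 and 0.0487. Further lower ones were GPA3 (-2.71, at least 1.16-fold, with -0.10 at its other probe set), ERG1 (-2.41, at least 3.57-fold), BC1L9 (-2.10), the aquaporin gene TIP1-2 (-2.04), the chitinase gene Cht2 (-1.92), HAK27 (-1.78) and the calmodulin-like gene CML16 (-1.70), with adjusted p between 0.00801 and 0.0426. In total 1992 probe sets passed, 1103 higher and 889 lower in the overexpression line, with 374 and 261 of them changed at least 2-fold. Of these, 597 (30%) also passed in the suppression line against the wild type, 3 in the overexpression line, and 1393 (69.9%) in neither. The count became 752 without overexpression replicate 1, 463 without overexpression replicate 2, 733 without suppression replicate 1 and 1018 without suppression replicate 3. AMT1-2, PP2C30, EIL1B, GLT2, SAT1, PHOT1A, SWEET14 and KAO kept their calls whichever array was left out, whereas BURP16 (2.77 to 4.76) lost its call without either overexpression array and GPA3 (-2.96 to -2.45) without any 1 array. Each of the other genes named by rank between the lines lost its call without overexpression replicate 2 and without at least 1 further array, with no change of sign.

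Of 16 nitrogen uptake and assimilation genes, 5 were lower in the overexpression than in the suppression line and 11 did not pass; 1 was higher and 5 lower adjusted over the list alone. The lower ones were the ammonium transporter genes AMT1-2, AMT3-2 (-1.31) and AMT3-3 (-1.55) and the glutamine synthetase genes GLN1-1 (-0.50) and GLN1-2 (-1.04). AMT3-2 (-1.57 to -1.06) lost its call without overexpression replicate 2, AMT3-3 (-1.86 to -1.24) without that or suppression replicate 3, GLN1-1 (-0.57 to -0.43) without either overexpression array or suppression replicate 1, and GLN1-2 (-1.37 to -0.71) without either suppression array. The list's median was 0.01, its mean -0.22 and its camera direction down (adjusted p = 0.46). It holds only genes with a matching symbol, so the calls need not show the direction of the whole process. GLT2, which was higher between the lines (1.85 ± 0.18, limma adjusted p = 0.00187), is not among its members. Of the 64 genes in the abscisic acid signalling list, 8 were lower and 3 higher, and 11 and 6 adjusted over the list alone (median -0.10, camera adjusted p = 0.324, fry adjusted p = 0.0433). The lower ones were PP2C30, PP2C68, OsPP2C08, OsPP2C09, OsABIL1, the protein kinase genes SAPK6 (-0.80) and SAPK7 (-0.63), and BZIP23, a transcription factor gene of this pathway (-0.90, adjusted p = 0.0167). OsPP2C10 (0.52), OsPP2C14 (0.59) and OsPP2C39 (0.94) were higher. These are type 2C phosphatase genes taken in by name, and whether they act in this pathway was not checked. OsPP2C10 (0.44 to 0.61) lost its call without any 1 array, OsPP2C39 (0.70 to 1.18) kept it only without suppression replicate 3, and OsPP2C08 (-0.91 to -0.63) only without wild-type replicate 2. OsPP2C14 (0.58 to 0.60), OsPP2C09 (-1.05 to -0.90), PP2C68 (-1.30 to -1.21) and SAPK6 (-0.91 to -0.69) lost theirs without any 1 transgenic array. OsABIL1 (-1.38 to -0.82) lost its call without either overexpression array, and SAPK7 (-0.69 to -0.57) and BZIP23 (-1.12 to -0.68) without those or suppression replicate 1.

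The cellulose and hemicellulose list was shifted downward between the lines (median -0.37, camera adjusted p = 0.00463; adjusted p = 0.86 with an estimated correlation and 0.0433 by fry). CESA6 (-0.83), CESA1 (-0.61), CSLC7 (-0.69), CSLC9 (-0.63) and CSLF6 (-0.48) were lower, CSLA5 (0.76) was higher, and 20 of 26 did not pass; 12 were lower and 2 higher adjusted over the list alone. CSLF6 (-0.56 to -0.40) lost its call without any 1 array, CSLC7 (-0.74 to -0.65) and CSLC9 (-0.71 to -0.54) without any 1 transgenic array and CESA1 (-0.69 to -0.54) without overexpression replicate 2, and CSLA5 (0.53 to 1.00) kept it only without overexpression replicate 1. Reference genes were also shifted downward (median -0.19, camera adjusted p = 0.00463; adjusted p = 0.86 with an estimated correlation and 0.0557 by fry), with ACT2 (-0.78 ± 0.08, adjusted p = 0.00203), GAPC3 (-0.54) and TUBB3 (-0.37, with other probe sets at -0.44 and 0.55) lower and 20 of 23 not past, and 9 lower and 1 higher adjusted over the list alone. GAPC3 (-0.62 to -0.46) lost its call without overexpression replicate 2 or suppression replicate 1, and TUBB3 (-0.42 to -0.32) kept it only without suppression replicate 1. TUBB2 read -0.29 (adjusted p = 0.0597). The 15 proteasome genes had a median of -0.16 (camera adjusted p = 0.02; adjusted p = 0.86 with an estimated correlation and 0.0939 by fry) with 0 called singly by limma, also adjusted over the list alone, and 5 with an unadjusted p under 0.05. OsPAA1 read -0.34 (adjusted p = 0.0665), TBP-1 -0.34 (0.0973), PBF1 -0.27 (0.151) and OsPBD1 -0.19 (0.176). The proteasome adjusted p was 0.104 without overexpression replicate 2, 0.0843 without suppression replicate 3 and 0.0702 after quantile normalization. The 3' to 5' ratio of actin was higher in the overexpression arrays, and the 18S signal lower in the suppression arrays, beside these 3 lists.

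Among 48 iron and metal homeostasis genes, 4 were lower in the overexpression than in the suppression line, led by MT4C (-1.51 ± 0.11, adjusted p = 0.00073), and 4 were higher, led by the iron transporter gene IRT1 (1.36 ± 0.25, adjusted p = 0.0198). Adjusted over the list alone, 5 were lower and 6 higher (median -0.05, camera adjusted p = 0.908). LHY was higher (1.06 ± 0.11, adjusted p = 0.00193) and PCL1 lower (-1.51 ± 0.15, adjusted p = 0.00187), and both kept these calls whichever array was left out. They were the called members of the 14 clock and flowering genes, of which 3 were higher and 1 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.328). Of the 15 splicing machinery genes 1 was lower, RSZ21A (-0.57 ± 0.11, adjusted p = 0.0279), as adjusted over the list alone (median -0.01, camera adjusted p = 0.951), and of the 10 light harvesting and photosystem genes 0 passed by limma and 1 had an unadjusted p under 0.05 (median 0.07). The root-preferred markers had AMT1-2 lower and IRT1 higher, 1 higher and 3 lower adjusted over the list alone, and a median of -0.44 (camera adjusted p = 0.392). The jasmonate list had 2 lower members, OPR-1 (-1.33) and OPR13 (-0.70), and LOX2.1 higher, 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.324). IRT1 (1.12 to 1.60) and OPR-1 (-1.63 to -1.03) lost their calls without overexpression replicate 2 or suppression replicate 1, OPR13 (-0.89 to -0.50) and LOX2.1 (0.95 to 2.01) without those or overexpression replicate 1, and RSZ21A (-0.63 to -0.50) without any 1 transgenic array.

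**Figure D3:**
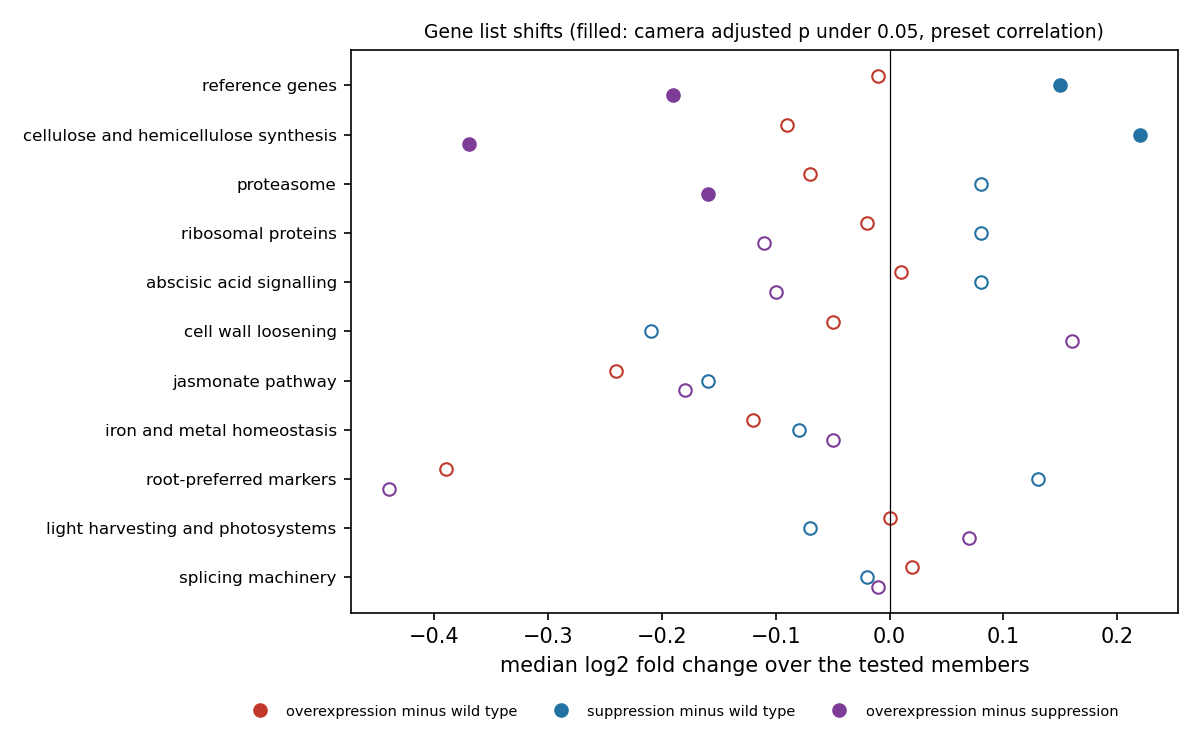
Median log2 fold change over the tested members of 11 gene lists in the 3 comparisons; filled points had a camera adjusted p under 0.05 with the preset correlation. Cellulose and hemicellulose synthesis lies at 0.22 for suppression minus wild type and at -0.37 for overexpression minus suppression. No filled point passed with an estimated correlation, a setting with little power at 3 residual degrees of freedom.

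Of the stress, defence and reference genes fixed individually beforehand, 12 were tested and none passed against the wild type in either line. In the overexpression and suppression lines respectively, DREB1A read 0.25 and -0.44, DREB2A -0.43 and -0.01, BZIP23 -0.22 and 0.68, salT -0.16 and 0.02, P5CS1 0.07 and 0.04, and PDC1 0 and -0.17. LEA19 read 1.74 ± 1.04 and 1.11 ± 1.04 (SE), the defence gene PBZ1 -0.61 and -0.20, CAT-A 0.15 and -0.17, CatB -0.10 and -0.10, ACT1 -0.03 and 0.24, and Lsi1 -0.52 and 0.09. Between the lines, BZIP23 passed and the others of these 12 did not, and its call was lost without either overexpression array or suppression replicate 1. RAB21, which passed between the lines (1.89, limma adjusted p = 0.0429), may be the gene fixed as RAB16A. The names used here do not pair them, so it was not counted among the 12. The moderated F test over the 3 groups passed 1141 probe sets.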

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

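The test on time of day below was set before its result was seen, and the other test of the same pattern was chosen afterwards. Of 75 named and 85 control probe sets examined, those listed here had the lines on opposite sides of the wild type, by at least 1.5-fold on each side, with a test of the difference between the lines past the threshold, or, for controls, both arrays of a line above both of the wild type and a mean over 1.5 times as high. Opposite sides by any amount were common, at 1737 (87.2%) of the 1992 probe sets called between the lines. That trait alone therefore does not set the listed genes apart.

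AMT1-2 differed between the lines by -2.54 on the log2 scale (limma adjusted p = 0.00241), with -1.63 in the overexpression line and 0.91 in the suppression line against the wild type. BURP16 differed by 3.77 (1.00 and -2.77; adjusted p = 0.0107), RAB21 by 1.89 (0.63 and -1.26; adjusted p = 0.0429) and KAO by 1.5 (0.66 and -0.85; adjusted p = 0.00428). ERG1 differed by -2.41 (-0.91 and 1.5; adjusted p = 0.0426), BC1L9 by -2.10 (-1.34 and 0.76; adjusted p = 0.0186), Cht2 by -1.92 (-0.99 and 0.93; adjusted p = 0.0314) and CML16 by -1.70 (-0.80 and 0.90; adjusted p = 0.0421). None of these 8 genes passed against the wild type in either line, and ERG1 differed between the lines by at least 3.57-fold. Without 1 array, each of them except AMT1-2 and KAO lost its call between the lines in at least 1 fit, and RAB21 read 1.05 without suppression replicate 3. The 5' control probe set for cyclophilin had a mean signal in the suppression line 1.65 times that in the wild type.

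PCL1 differed between the lines by -1.51 (-0.62 in the overexpression line and 0.89 in the suppression line; adjusted p = 0.00187), and LHY lay the other way, at 0.35 ± 0.11 and -0.71 ± 0.11 (SE). A different time of day at harvest could move clock genes, but the evening genes PRR1 and GI had a mean log2 fold change of -0.01 ± 0.07 in the suppression line, which lies within 1 standard error of 0 and leaves this explanation open. The suppression of OsSKIPa stays open too. Of LHY and PCL1, 2 lay on the other side of the wild type in the overexpression line by more than 1 standard error, but neither passed there, and PCL1 was picked out because the lines lie on opposite sides, so this gives no support. The line, its inserted construct and its selection drug are confounded with the suppression of OsSKIPa. The daytime genes PRR37, PRR73 and PRR95 read -0.27, -0.07 and 0.09 in the suppression line, and none passed.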

How the results depend on the processing

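The counts without reporter probe sets were chosen after the data were seen, and the other settings before. No call of a named gene or list turned its direction under any alternative. Scaling by quantiles or the 75th percentile called 14 or 15 of the 15 overexpression probe sets, 656 or 643 of the 698 for suppression, and 1934 or 1941 of the 1992 between the lines. Of 52 named gene calls, 52 held with the 75th percentile scaling and both other pseudocounts, 51 with quantile normalization, 48 with robust eBayes, 43 with only the 2 groups compared, 35 with no filter, 12 with the replicate block and 3 without the variance trend, and 38 of the 38 still tested held with the filter at the 75th percentile. With 1 array left out, 29 to 32 held, 15 in each such fit and 4 (GLK2, GPA3, PXG and TGAL11) in none. Of 107 further calls, those of list members and of the overexpression probe sets, 38 to 72 held in these fits.

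Without the filter the counts fell to 425 for suppression against wild type, 1255 between the lines and 668 by the F test. With the filter at the 75th percentile, 7 passed for overexpression and 5 in both lines. eBayes without the trend left 0 for overexpression against wild type (unadjusted p under 0.05: 2159 in limma with the trend), 26 for suppression, 69 between the lines, 1 by the F test and 0 in both lines. A fit of only the 2 groups compared gave 7 in both lines and 2 lists for overexpression, and the share of higher calls there was 53.3% against 80%. A 2-fold minimum left 322 and 635, and an unadjusted p with 2-fold gave 387 for overexpression and 1233 between the lines. Counted as genes, 6 passed for overexpression. Without reporter probe sets the counts were 11, 688, 1987, 1129 by the F test and 10 in both lines. The cause of these shifts was not tested, apart from the fewer or more probe sets that the filters leave.

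The replicate numbers do not pair the samples: deviations of equally numbered arrays correlated at -0.015 (overexpression and wild type), -0.066 (the lines) and -0.001 (suppression and wild type). With the replicate block the counts were 11, 99 and 319, with 109 by the F test, 5 in both lines in the same direction and 1 in opposite directions, and 2 lists for overexpression. Its lists gave an adjusted p of 0.0563 for cellulose in suppression and 0.0708 for the proteasome between the lines. Suppression shares the number 1 alone with the other groups.

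For lists, quantile normalization left 1 in suppression, and 75th percentile scaling gave 1 in overexpression. An estimated correlation left 0 in suppression and 0 between the lines, while fry and the mean of all probe sets each left 0 in suppression.

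With 1 array left out, overexpression gave 5 (without overexpression replicate 1) to 36 (without wild-type replicate 2), suppression 171 (without wild-type replicate 2) to 583, the lines 463 (without overexpression replicate 2) to 1410, the F test 352 (without suppression replicate 1) to 706, and both lines 3 (without overexpression replicate 1) to 23 (without wild-type replicate 2). Lists past the threshold numbered 0 to 4 for overexpression, 0 to 7 for suppression and 2 to 4 between the lines. The lone array of a group was assumed to vary like the other groups. Alternatives for OsSKIPa itself were not run, since no probe set carries its name.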

Other observations

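The tests on the probe sets called in both lines and on the reporter probe sets were chosen after the results they bear on had been seen, and the list tests before. Several gene groups not described above had called members between the lines. Among 26 heat shock proteins and chaperones, HSP17.9A (1.16 ± 0.16, limma adjusted p = 0.00677) and HSP18.8 (1.00 ± 0.15, adjusted p = 0.0107) were higher in the overexpression than in the suppression line, and HSP18.0 (-0.67 ± 0.10, adjusted p = 0.00888) and the endoplasmic reticulum chaperone gene BIP1 (-0.61 ± 0.10, adjusted p = 0.0154) were lower. Adjusted over the list alone there were 4 in each direction, and the list did not pass (camera adjusted p = 0.46). HSP18.8 (0.82 to 1.19) lost its call without overexpression replicate 2 or suppression replicate 1, and BIP1 (-0.71 to -0.50) without overexpression replicate 2 or suppression replicate 3. Of 22 pathogenesis-related genes, GER1 (1.04) and GER3 (1.2) were higher and GER7 (-0.80), Cht2 and Cht11 (-1.08) lower, with 3 in each direction adjusted over the list alone (camera adjusted p = 0.831). GER7 (-0.85 to -0.76) and Cht11 (-1.26 to -0.90) lost their calls without any 1 transgenic array, GER1 (0.74 to 1.33) and GER3 (0.94 to 1.45) without either overexpression array or suppression replicate 1, and Cht2 (-2.46 to -1.38) without either overexpression array or suppression replicate 3.

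Reactive oxygen scavenging genes included 3 lower members of 21 between the lines, APX6 (-0.48), APX7 (-0.74) and PRXIIE-2 (-0.41), with 6 lower and 2 higher adjusted over the list alone (median -0.19, camera adjusted p = 0.163). APX6 (-0.54 to -0.41) and PRXIIE-2 (-0.44 to -0.37) lost their calls without any 1 array and APX7 (-0.90 to -0.58) without any 1 transgenic array. In cytokinin metabolism and response, CKX11 (0.90), HK5 (0.61) and LOGL7 (0.64) were higher of 28, and 3 were higher and 1 lower adjusted over the list alone (median -0.01, camera direction up, adjusted p = 0.811). HK5 (0.59 to 0.64) and LOGL7 (0.62 to 0.67) lost their calls without any 1 transgenic array and CKX11 (0.65 to 1.15) without either overexpression array or suppression replicate 1. Of 7 LEA proteins and dehydrins, RAB21 was higher and RAB16C (-1.55) and Dhn1 (-0.61) were lower, with 2 in each direction adjusted over the list alone, a median of -0.28 and a mean of 0.10 (camera adjusted p = 0.908). RAB16C (-1.96 to -1.13) kept its call only without suppression replicate 1 and RAB21 (1.05 to 2.72) only without suppression replicate 1 or 3, and Dhn1 (-0.69 to -0.53) lost it without overexpression replicate 2 or either suppression array. The expansin-like genes EXLA1 (0.76) and EXLA2 (0.83) were higher and the expansin gene EXPB6 (-0.50) lower among 24 cell wall loosening genes, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.426). EXPB6 (-0.61 to -0.39) lost its call without any 1 array, EXLA2 (0.80 to 0.87) without any 1 transgenic array and EXLA1 (0.68 to 0.84) without overexpression replicate 2.

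The 13 probe sets called in both lines moved in the same direction in both, and 0 moved in opposite directions. If the lines change OsSKIPa as labelled, these directions argue against a cause that rises and falls with its level. That level was not measured here, and the shared wild-type arrays favour calls in the same direction. Independent lists would give only 0.16 and 0.029 calls in opposite directions. Some probe sets were called in opposite directions when overexpression replicate 1 or 2 or suppression replicate 3 was left out. Without wild-type replicate 1, 10 probe sets were called in both lines in the same direction, and for 10 of them (100%) the left-out array lay on the same side by at least 0.5 of the change, while without wild-type replicate 2 it did so for 12 of 23 (52.2%), where the 1000 probe sets of nearest signal give 0.033 by chance, and the ones for which it did not lie outside the 13. This argues against chance error of the shared wild-type arrays for the 10 of the 13 covered by either test, and it stays open for the other 3 (LOC4343074 and 2 unnamed probe sets), which lost the call in 1 line or both when either array was left out, so that no left-out array is independent of their choice. The 13 were chosen with wild-type replicate 2 in the fit, so the lack of failures among them is no evidence. For the whole set called without that array, 52.2% lies below the 80% set for this test. Chance error stays open for that set as a whole. A gene or probed sequence absent from or silent in these wild-type plants stays open. Of the 11 shared rises, 10 had both wild-type arrays below the array median, which is not a call of absence. With 1 probe set per target it was 7 of 8 (87.5%). Among rises of the nearest size in the suppression line alone it was 5 of 8 (62.5%; Fisher's exact test, two-sided, p = 0.569). That test asks only whether shared rises are dim in the wild type more often than other large rises. With 8 of each it has little power, so it cannot decide this explanation. An effect of transformation or culture common to both lines was not tested.

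Each transgenic line had its own reporter probe sets high. At the clearest reporter, the lowest array of the line exceeded the highest value or array median of the other groups at least 188-fold in the overexpression line and at least 25.3-fold in the suppression line, which argues against 1 array carrying the label of another group. Further reporters of the suppression line gave a ratio of 8.75, with 1 overexpression array also above its median, and at least 3.14-fold. Of all 64 reporter probe sets, 0 had both wild-type arrays above the array median, against 1 in the overexpression and 4 in the suppression line. These counts do not decide whether a selection marker or other part of the inserted construct was measured. The sequences that these reporter probe sets target were not looked up here. An exchange of the labels of the whole lines was not tested.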
